A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

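Polyadenylated RNA was measured in 6 cultures of the diploid budding yeast strain BY4743, 3 naive and 3 carrying the [ESI+] state, grown in rich glucose medium (YPD) to an optical density of about 0.5, per the labels' protocols. Total RNA was extracted with hot phenol and enriched with oligo-dT beads. The cDNA was sheared to 200 to 400 bp with a peak near 300 bp, made into libraries and sequenced in paired ends on an Illumina instrument, per the labels' protocols. Whether the libraries kept the strand was not given in the sources used here.

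Per the submitters' processing notes, the authors quantified transcripts with kallisto 0.43.1 against the yeast genome build R64. The deposited tables hold, for each library, estimated counts and TPM values for 17906 transcript isoforms, per the file headers. Estimated counts are fragments that the authors' quantification assigned to an isoform, with fragments that match several isoforms shared out among them. TPM values are abundances that the authors' tool scaled for transcript length and to the same total in each library. The isoforms belong to 2850 genes, 44.3% of the 6431 nuclear genes of the R64 reference annotation, so every count below is over a partial set of genes. Kallisto's options and the origin of the isoform models were not given in the sources used here. A match by systematic name to the R64 reference gave symbols and coordinates for 2849 genes. Coordinates are 1-based coding spans without untranslated regions.

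The estimated counts were summed over the isoforms of each gene and rounded to whole numbers. Total estimated counts were 4361435, 1080941 and 5934050 in naive replicates 1 to 3 and 1937568, 3896490 and 316485 in ESI+ replicates 1 to 3. Genes with low counts were removed with edgeR's default filter (minimum count 10), which left 2844 genes. Library sizes were scaled by the TMM method, and normalised counts (CPM) are scaled to those sizes. ESI+ was compared with naive by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are log2, ESI+ minus naive, and each standard error (SE) was derived from the fold change and the F statistic of that test. The replicate number was not used as a block in this comparison. In data simulated from the real means and library sizes, with 2844 genes, edgeR called 8% of genes changed 2-fold, 61% of genes changed 4-fold and 0.11% of unchanged genes in the comparison of ESI+ with naive. Apart from these changes, all simulated libraries shared the same mean profile. The rates therefore do not cover libraries whose abundance profiles differ, as those of the real ESI+ libraries do.

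The tests, the gene lists and the alternatives were chosen before the data were examined, except those named as added later. Gene lists of yeast pathways and complexes, 45 in number, were tested with camera from limma 3.58.1 where at least 3 members were tested, with a preset correlation of 0.01, and again with an estimated correlation. The fry test was run on the same lists and on the subtelomeric genes. A gene counted as subtelomeric when its nearest end lay within 20 kb of a chromosome end, and shares of called genes were compared with all other tested nuclear genes by a two-sided Fisher's exact test. The median fold change of each chromosome was compared with that of all genes, in the fit and in each library against the mean of the naive libraries, and departures over 0.3 were reported. List medians were also ranked among 10000 random lists matched on mean expression over all libraries, a check added after seeing the data.

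Genes were named by a rule. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose 3 ESI+ values all lay on the same side of the 3 naive values and whose higher group had a mean CPM of at least 5. It added all listed Set3 complex, strain marker and mating-type genes, up to 4 members with the smallest adjusted p of each list that passed camera, and the 8 subtelomeric genes with the smallest adjusted p. Any other gene named was chosen after its values were seen. Genes with a copy at 95% identity over at least 50% of their length (blastn 2.17.0, 39 genes) and genes that overlap another gene (44) were marked as uncertain, because their reads can be shared.

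The alternatives were DESeq2 size factors in edgeR, DESeq2 1.42.0, limma on log2 TPM with pseudocounts of 1 and 0.1 (TPM of at least 1 in 3 libraries), effective-length offsets, no filter, a filter of 50 counts in 3 libraries, the replicate number as a block, removal of the 20 most abundant genes, leaving out each library, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and limits of 10, 30 and 50 kb for subtelomeric genes. Alternatives added after seeing the data were ESI+ replicate 1 alone against naive, weights for library quality in limma, subtraction of a length-proportional background set from the 5th percentile of counts per kb in each library, and the subtelomeric comparison without the genes of chromosome XIII, left out of the subtelomeric group alone or of both groups.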

Results

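The series measured transcripts in naive and [ESI+] cells labelled BY4743, a diploid laboratory strain of Saccharomyces cerevisiae. [ESI+] is a heritable, prion-like state that has been tied to Snt1, a subunit of the Set3 histone deacetylase complex, and to the expression of genes near chromosome ends. Each group held 3 biological replicates. Total estimated counts were 4361435, 1080941 and 5934050 in the naive libraries and 1937568, 3896490 and 316485 in the ESI+ libraries, over 2850 listed genes. In ESI+ replicate 3, the shallowest library, 78 genes had no counts. The glycolytic gene TDH3 took 10.8% of the counts of naive replicate 1 and 2.83% of those of ESI+ replicate 2. The 100 most abundant genes held 57.0% to 61.1% of the counts in the naive libraries, and 51.6%, 28.3% and 41.8% in ESI+ replicates 1, 2 and 3. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.928 to 0.953 among naive libraries, 0.900 to 0.911 between ESI+ replicate 1 and the naive libraries, and 0.600 between ESI+ replicates 2 and 3. Over the 713 genes least abundant in naive cells, Spearman's rho between counts and transcript length was 0.761 in ESI+ replicate 2 and 0.04 to 0.425 in the other libraries.

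**Figure D1:**
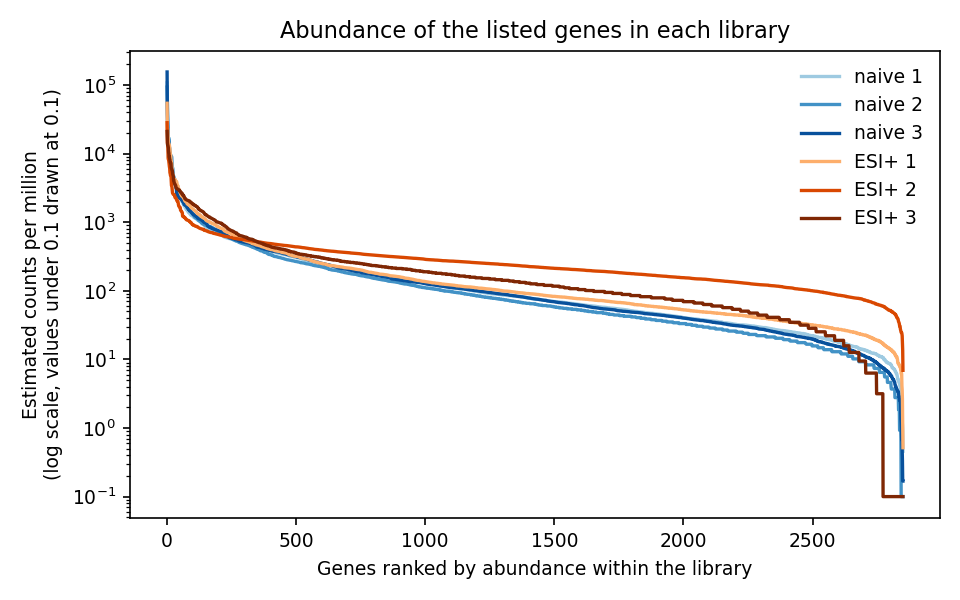
Estimated counts of the listed genes, scaled to the library total as CPM (log scale) against their rank within each library, 1 line per library. ESI+ replicate 2 has the flattest line, with 28.3% of its counts in its 100 most abundant genes.

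The strain and mating-type genes were read first, as a check of the labels. URA3, a uracil synthesis gene that BY4743 lacks by design, had 32.3, 20.4 and 254.8 normalised CPM in naive replicates 1 to 3 and 17.8, 26.3 and 333 in ESI+ replicates 1 to 3. Its values in naive replicate 3 and ESI+ replicate 3 go against the strain label, and their source was not tested. In ESI+ replicates 1 and 2 it had 33 and 199 counts over 930 bp. These were near or under the estimated length-proportional background of 32.56 and 295.2 counts per kb there. In naive replicates 1 and 2 URA3 had 114 and 15 counts, above the background of 42.06 and 7.264 counts per kb there. The source of those counts was not tested either. HIS3, a histidine synthesis gene that is partly deleted in this strain, had 38.7 ± 10.3 normalised CPM in naive and 185 ± 233 in ESI+ libraries (SD, n = 3), with 453 in ESI+ replicate 3. MET17, a sulfur assimilation gene, had 75.1 ± 29.7 and 126 ± 88.6 (SD, n = 3), and it overlaps another gene. The a-factor gene MFA1, which is repressed in a/alpha diploids, had 0.76 ± 0.71 and 10.1 ± 5.74 normalised CPM (SD, n = 3). These came from 5, 0 and 4 counts in naive and 7, 86 and 6 in ESI+ replicates 1 to 3. Over 286 bp, the counts in ESI+ replicates 1 and 2 were near or under the estimated background there. The count in ESI+ replicate 3 was above it (1.978 counts per kb). Its log2 fold change of 3.25 (SE 1.25) did not pass with edgeR (adjusted p = 0.0963) or with effective-length offsets (2.49, adjusted p = 0.232). MFA1 passed with DESeq2 (adjusted p = 0.0343) and with limma on log2(TPM + 1) (adjusted p = 8.88e-04), where the median of all genes was 0.65. Without ESI+ replicate 2 it was not tested. The other a-factor gene MFA2 had 0.55 ± 0.76 and 3.27 ± 4.76 normalised CPM, and the a-agglutinin subunit gene AGA2 had 3.04 ± 1.69 and 35.3 ± 50.04 (SD, n = 3). AGA2 had 0.54, 12.7 and 92.65 in ESI+ replicates 1, 2 and 3, with replicate 1 below every naive library. In ESI+ replicate 2, MFA2 and AGA2 had 66 and 96 counts over 332 and 523 bp, under the estimated background there. The G protein beta subunit gene STE4, from the list of haploid-specific genes, had 32.5 ± 11.8 normalised CPM in naive and 59.4 ± 33.4 in ESI+ libraries (SD, n = 3). Its log2 fold change was 0.90 (SE 0.60, edgeR adjusted p = 0.345), or 0.31 without ESI+ replicate 2. CPR1, a cyclophilin, was the only listed gene of the Set3 complex, with 2467 ± 596 normalised CPM in naive and 1013 ± 573 in ESI+ libraries (SD, n = 3; log2 fold change -1.29, SE 0.73, edgeR adjusted p = 0.267).

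The comparison of ESI+ with naive cells asked which transcripts differ between the states. The genes called higher in ESI+ cells included the silencing gene SIR1, the poly(A) polymerase gene TRF5 and the G1 cyclin gene PCL1, each of low abundance in naive cells. Genes that were lower included the abundant ERG25 of sterol synthesis, HSP60 of mitochondrial protein folding and OST3 of protein glycosylation. TRF5 had 7.11 ± 2.02 normalised CPM in naive and 114 ± 91.8 in ESI+ libraries (SD, n = 3), a log2 fold change of 3.97. ERG25, a sterol C-4 methyl oxidase gene, had 3290 ± 1517 and 314 ± 258 (SD, n = 3), a log2 fold change of -3.39. In total 178 genes were higher and 47 lower among 2844 tested (edgeR, adjusted p under 0.05), with log2 fold changes of 1.43 to 4.88 and of -3.39 to -1.42.

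**Figure D2:**
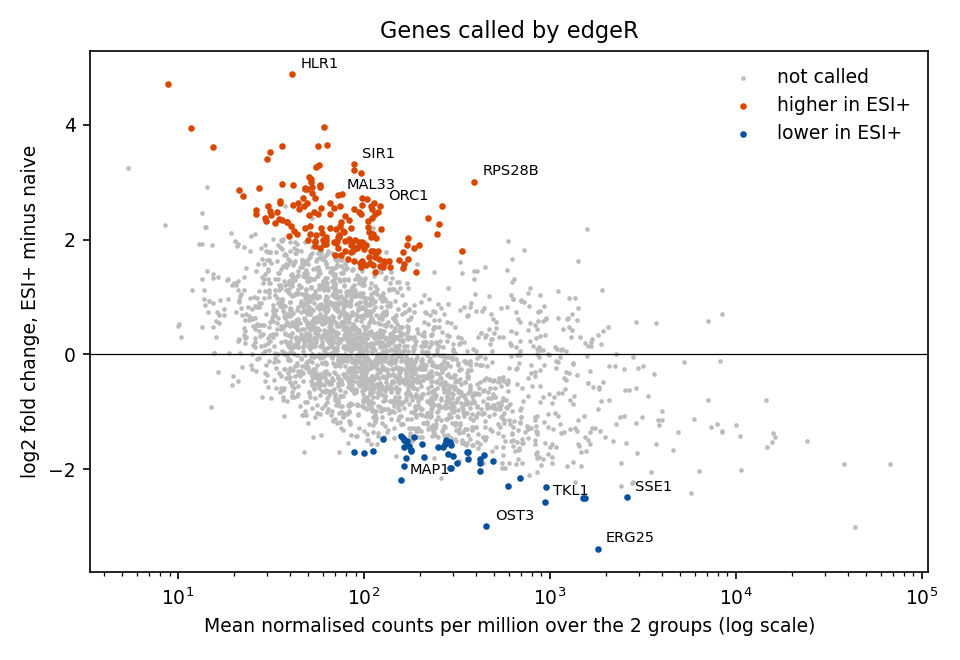
Log2 fold change (ESI+ minus naive) of each tested gene against its mean normalised CPM (log scale), with 178 genes called higher and 47 called lower by edgeR in colour. The higher calls lie at low abundance and the lower calls at high abundance.

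The 12 largest rises under the rule came from varied functions. HLR1 (YDR528W), linked to cell wall regulation, had the largest log2 fold change, 4.88 (SE 0.95, edgeR adjusted p = 0.0058), with 4 counts in ESI+ replicate 3 and none in naive replicate 2. The sulfiredoxin gene SRX1 was second, at 4.72 (SE 1.21, adjusted p = 0.0194), with 4, 0 and 2 counts in the naive libraries and 8, 300 and 3 in the ESI+ libraries. TRF5 (YNL299W, chromosome XIV, 66517 to 68445; SE 0.67, adjusted p = 0.00331) came after it, and YEH1, a steryl ester hydrolase gene, had 3.63 (SE 0.64, adjusted p = 0.00331). MHT1, a methyltransferase gene of methionine synthesis, rose by 3.64 on the log2 scale, PDH1, a gene of propionate metabolism, by 3.52, PCL1 by 3.41 and SEN34, a tRNA splicing endonuclease subunit, by 3.30. MTO1, needed for mitochondrial tRNA modification, rose by 3.65 and overlaps another gene. The open reading frames YGR050C and YFL012W also passed, with 183 and 460 counts in ESI+ replicate 2 and 14 and 4 in ESI+ replicate 3. Without ESI+ replicate 2 the log2 fold changes of MTO1, PCL1, YFL012W, PDH1 and HLR1 were 1.92, 1.61, 2.37, 2.43 and 3.52. SIR1 (YKR101W, chromosome XI, 640540 to 642504) rose from 16.5 ± 6.09 to 160 ± 113 normalised CPM (SD, n = 3; log2 fold change 3.31, SE 0.60, edgeR adjusted p = 0.00331).

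The 12 largest falls came from genes with mean naive values of 262 normalised CPM (MAP1) to 4383 (SSE1). ERG25 (YGR060W, chromosome VII, 610564 to 611493; SE 0.83, edgeR adjusted p = 0.0147) and ERG1, the squalene epoxidase gene (log2 fold change -2.03, SE 0.55, adjusted p = 0.0247), act in sterol synthesis. OST3, a subunit of the oligosaccharyltransferase, fell by 3.00 on the log2 scale (SE 0.83, adjusted p = 0.0359), and TKL1, the transketolase gene, by 2.57 (SE 0.73, adjusted p = 0.0333). HSP60, the mitochondrial chaperonin gene, fell by 2.51 and the Hsp110 gene SSE1 had a log2 fold change of -2.49. SSZ1 and ZUO1, which form the ribosome-associated chaperone complex, had log2 fold changes of -2.30 and -2.16. NOP56, a small nucleolar ribonucleoprotein gene, fell by 2.51, from 2615 ± 1209 normalised CPM in naive to 461 ± 353 in ESI+ libraries (SD, n = 3). The methionine aminopeptidase gene MAP1 had a log2 fold change of -2.19, the cyclin-like gene CLG1 of -2.31 and the heme synthesis gene HEM13 of -1.99, and MAP1 and CLG1 had -1.35 and -1.51 without naive replicate 3. Each of the 47 lower genes and 170 of the 178 higher genes had its 3 ESI+ values on the same side of all 3 naive values. Calling from the same libraries favours such genes, so these counts only describe the calls. Of all tested genes 29.9% were separated in this way, against 10% by chance for a single gene. Because the genes share the same libraries, the difference between these shares is not a test.

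The counts depended on which libraries were included. Without ESI+ replicate 2, edgeR called 2 genes higher, RPS28B and RPS29A, and 0 lower (566 genes at an unadjusted p under 0.05), and without naive replicates 1, 2 and 3 it called 87, 63 and 71 higher and 14, 6 and 4 lower. Without ESI+ replicate 1 the counts were 249 and 87, and without ESI+ replicate 3 they were 331 and 43. Of the 178 higher and 47 lower genes, 177 and 47 were tested without ESI+ replicate 2 and all of these had the same sign, with median log2 fold changes of 1.67 and -1.69. They were chosen in a fit that held the remaining libraries, so a kept sign was favoured beforehand. Of the 178 higher genes, 140 were among the 711 genes least abundant in naive cells, whose median log2 fold change was 1.17, and 33 of the 47 lower genes were among the 711 most abundant, whose median was -0.83. DESeq2 called 241 genes higher and 145 lower, including 178 and 46 of those above. Limma on log2(TPM + 1) called 138 and 32, including 54 and 10 of those above, on a scale where the median of all genes was 0.65.

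Among the fixed lists, 29 had at least 3 tested members and 6 passed camera. Heat shock genes and glycolytic genes were lower as groups, as were genes of amino acid synthesis and ribosome biogenesis, while ribosomal protein genes and silencing factors were higher. None of the 6 passed with an estimated correlation, where the smallest adjusted p over all lists was 0.673. Ergosterol synthesis genes had 1 higher, 3 lower and 15 uncalled members, with 1 higher and 4 lower adjusted over the list alone; the list did not pass camera (adjusted p = 0.0696), and it was the list that passed limma's fry test, which asks whether a list's genes move in a common direction on balance (lower, adjusted p = 0.0289). Among 10000 random lists matched on mean expression, the medians of heat shock, glycolysis and ribosomal protein genes lay at percentiles 1.09, 1.57 and 100, and those of ribosome biogenesis, amino acid synthesis and silencing genes at 2.73, 7.57 and 97.3, inside the central 95%. Without ESI+ replicate 2 these percentiles were 1.16, 1.57 and 100, and 0.09, 7.30 and 82.2. For the 6 lists that passed camera, fry's adjusted p in limma was 0.273 to 0.637. All 20 heat shock genes had negative fold changes, with a median of -1.17 (camera adjusted p = 1.51e-05, and adjusted p = 0.673 with an estimated correlation). HSP60 (SE 0.74, edgeR adjusted p = 0.0386) and SSE1 (SE 0.77, adjusted p = 0.045) passed over all genes, and 6 passed when adjusted over the list alone. The Hsp90 genes HSC82 and HSP82 had log2 fold changes of -2.42 (SE 0.81, edgeR adjusted p = 0.0594) and -2.23 (SE 0.76, adjusted p = 0.0641). The list median relative to the naive mean was -1.20, -1.96 and -0.43 in ESI+ replicates 1, 2 and 3.

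All 16 glycolytic genes had negative fold changes, with a median of -1.36 (camera adjusted p = 7.61e-05, and adjusted p = 0.673 with an estimated correlation). None of them passed with edgeR over all genes or adjusted over the list alone, 2 had an unadjusted p under 0.05, and DESeq2 called 3 lower and limma on log2(TPM + 1) called 0. The enolase gene ENO2 had 60100 ± 28370 normalised CPM in naive and 16010 ± 8684 in ESI+ libraries (SD, n = 3; log2 fold change -1.91, SE 0.88, edgeR adjusted p = 0.165). GPM1, the phosphoglycerate mutase gene, and HXK2, a hexokinase gene, had log2 fold changes of -1.53 (SE 0.83, adjusted p = 0.238) and -1.35 (SE 0.71, adjusted p = 0.225). TDH3 had -1.91 (SE 0.92, adjusted p = 0.186) and has a near-identical copy. With the 20 most abundant genes removed, which left 5 of the 16 members, the median was -1.08 and the list did not pass (camera adjusted p = 0.072).

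Amino acid synthesis genes had a median log2 fold change of -0.63 over 30 tested genes (camera adjusted p = 0.0131, and adjusted p = 0.673 with an estimated correlation). LEU1, which encodes isopropylmalate isomerase, was the member that passed (log2 fold change -1.86, SE 0.58, edgeR adjusted p = 0.046), and 0 passed adjusted over the list alone, where 8 had an unadjusted p under 0.05 on the lower side; DESeq2 called 3 and limma on log2(TPM + 1) called 0. ILV3 had -1.61 (SE 0.60, adjusted p = 0.0875) and ILV1 -1.26 (SE 0.47, adjusted p = 0.0902), and LYS20, with a near-identical copy, had -1.34 (SE 0.48, adjusted p = 0.0754), or -0.77 without naive replicate 3. The list did not pass without ESI+ replicate 2 (median -0.54, camera adjusted p = 0.0887), without naive replicate 3 (-0.47, adjusted p = 0.0807) or with ESI+ replicate 1 alone (-0.39, adjusted p = 0.0926).

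Ribosome biogenesis genes had a median of -0.27 over 45 genes (camera adjusted p = 0.0414, and adjusted p = 0.673 with an estimated correlation), with 3 lower, 42 not called, and 3 lower adjusted over the list alone. The 3 were NOP56 (SE 0.79, edgeR adjusted p = 0.046), the rRNA methyltransferase gene NOP2 (log2 fold change -1.61, SE 0.48, adjusted p = 0.0386) and the nucleolin gene NSR1 (-1.57, SE 0.45, adjusted p = 0.0342), while GAR1 had -1.86 (SE 0.60, adjusted p = 0.0546). The list did not pass without naive replicate 2 (median -0.14, camera adjusted p = 0.123), naive replicate 3 (-0.18, adjusted p = 0.104) or ESI+ replicate 3 (-0.44, adjusted p = 0.0845), and without ESI+ replicate 1 its median turned to 0.03 (adjusted p = 0.229). Nor did it pass with DESeq2 (median -0.26, adjusted p = 0.0838), effective-length offsets (-0.28, adjusted p = 0.0558), the filter of 50 counts (-0.22, adjusted p = 0.0725) or background subtraction (-0.31, adjusted p = 0.058).

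Ribosomal protein genes had a median of 0.44 over 133 genes, with 9 higher, 0 lower and 124 not called by edgeR, and 6 higher adjusted over the list alone, while DESeq2 called 13 higher and limma on log2(TPM + 1) called 44 (camera adjusted p = 0.0131, and adjusted p = 0.799 with an estimated correlation; 1 lower at an unadjusted p under 0.05, and 0 lower by DESeq2 or limma on log2(TPM + 1)). The higher genes included RPS28B (log2 fold change 3.01, SE 0.67, edgeR adjusted p = 0.00928; 1.94 without ESI+ replicate 3), RPS29A (2.58, SE 0.53, adjusted p = 0.00554), RPL18B (2.61, SE 0.54, adjusted p = 0.00554) and RPL22B (2.63, SE 0.61, adjusted p = 0.00994). The list median relative to the naive mean was 0.72, -0.98 and 1.13 in ESI+ replicates 1, 2 and 3. The list did not pass without naive replicate 1 (median 0.37, camera adjusted p = 0.113) or ESI+ replicate 1 (0.39, adjusted p = 0.424), and without ESI+ replicate 3 its direction turned (median 0.02, adjusted p = 0.803), and 21 of its genes have a near-identical copy.

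All 6 listed silencing factors had positive fold changes, with a median of 1.41 (camera adjusted p = 0.0131, and adjusted p = 0.673 with an estimated correlation). SIR1 and ORC1, the origin recognition gene that recruits silencing proteins (log2 fold change 2.58, SE 0.52, edgeR adjusted p = 0.00554), passed over all genes, and 3 passed adjusted over the list alone. The Ku subunit gene YKU70 had 1.24 (SE 0.45, adjusted p = 0.0789) and the sirtuin gene HST3 had 1.58 (SE 0.78, adjusted p = 0.199), or 0.24 without ESI+ replicate 2. The list did not pass without ESI+ replicate 2 (median 0.57, camera adjusted p = 0.139), with ESI+ replicate 1 alone (0.68, adjusted p = 0.0717), with background subtraction (1.93 over 5 genes, adjusted p = 0.0739), or with limma on log2(TPM + 1) (1.62, adjusted p = 0.199) and log2(TPM + 0.1) (1.65, adjusted p = 0.241), where the median of all genes was 0.65.

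**Figure D3:**
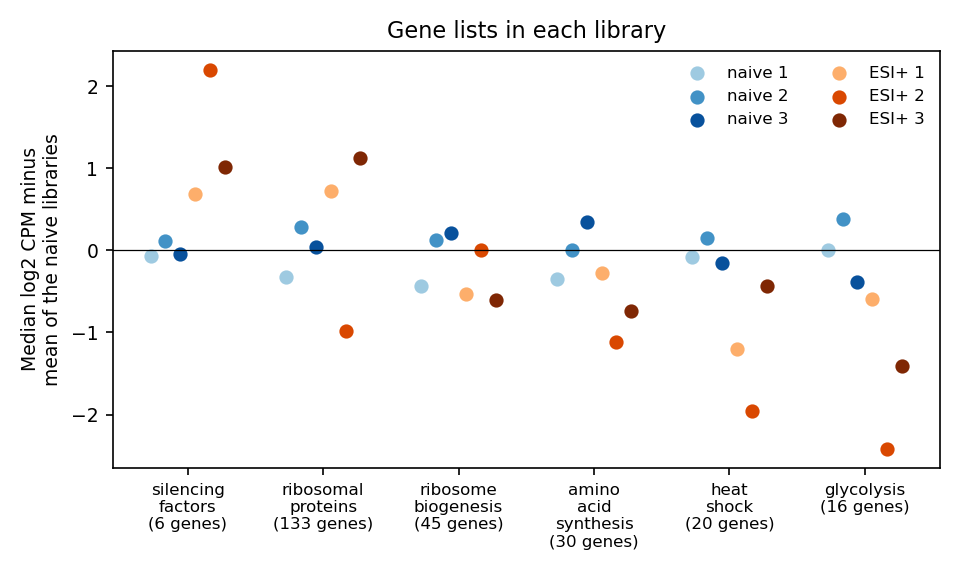
Median log2 CPM of the tested genes of each list that passed camera, relative to the mean of the naive libraries, with 1 point per library. Heat shock and glycolysis medians lie below 0 in each ESI+ library, and the ribosomal protein median is -0.98 in ESI+ replicate 2 and above 0 in ESI+ replicates 1 and 3.

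Genes near chromosome ends were compared with all others because of the state's reported tie to them. MAL33, a maltose regulator gene, PHO89, a phosphate transporter gene, MHT1 and VAC17, a vacuole inheritance gene, were higher in ESI+ cells, as were COX14, SEA4 and the open reading frame YML131W. These were 7 of the 29 tested genes within 20 kb of an end (24.1%), against 171 of 2814 others (6.08%; two-sided Fisher's exact test, p = 0.00161). MAL33 (YBR297W, chromosome II, 800523 to 801929) had 18.0 ± 6.38 normalised CPM in naive and 127 ± 72.9 in ESI+ libraries (SD, n = 3; log2 fold change 2.78, SE 0.57, edgeR adjusted p = 0.00554). PHO89 rose by 2.91 on the log2 scale (SE 0.71, adjusted p = 0.0163), VAC17 by 2.55 (SE 0.62, adjusted p = 0.0136), and SEA4 by 2.21 (SE 0.68, adjusted p = 0.0485), and without ESI+ replicate 2 their log2 fold changes were 1.41, 1.30 and 0.51. YML131W and COX14, both on chromosome XIII, rose by 1.81 and 1.62, and SRY1, a hydroxyaspartate dehydratase gene, had 1.21 (SE 0.51, adjusted p = 0.126), while COX14 had 0.98 without ESI+ replicate 3 and SRY1 0.65 without ESI+ replicate 2. None of the 29 was called lower by edgeR (0 at an unadjusted p under 0.05 on the lower side), against 47 of 2814 others (1.67%; Fisher's exact p = 1).

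The median log2 fold change was 0.57 within 20 kb, against 0.07 over all genes (camera p = 0.00228, and p = 0.234 with an estimated correlation). For a common direction, fry's p in limma was 0.101 within 20 kb, 0.215 within 10 kb, 0.192 within 30 kb and 0.246 within 50 kb. The subtelomeric genes therefore did not pass fry at any of these limits. By distance, 0 of 4 genes within 10 kb, 7 of 25 at 10 to 20 kb, 9 of 54 at 20 to 30 kb, 20 of 132 at 30 to 50 kb and 142 of 2628 beyond 50 kb were called higher. The 29 genes are 11.2% of the 259 reference genes of that zone, and lists of the PAU, COS, flocculin and Y' helicase families had no member in the tables. Without ESI+ replicate 2, 0 of the 29 were called and the median was 0.35 (camera p = 0.0236), and without naive replicate 3, 3 were called (Fisher's exact p = 0.0341). Without ESI+ replicate 3, 6 of the 29 were called (Fisher's exact p = 0.139). With the genes of chromosome XIII left out of both groups, 5 of 23 were called, against 136 of 2567 (Fisher's exact p = 0.00676).

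Genes of chromosome XIII were higher as a group in ESI+ cells. Their median log2 fold change lay 0.42 above that of all genes, over 253 tested genes, with 37 called higher and 0 lower. ORC1 and YKU70 are on this chromosome. In each library against the naive mean, the departure of chromosome XIII was 0.47, 0.57 and 0.41 in ESI+ replicates 1, 2 and 3, and -0.03, -0.01 and 0.02 in naive replicates 1, 2 and 3. Chromosomes I, VI and IX lay 0.39, 0.47 and 0.33 above all genes and chromosome IV 0.31 below. Over the 15 chromosomes other than XIII, Spearman's rho between departure and chromosome length was -0.696, -0.671 and -0.711 in ESI+ replicates 1, 2 and 3, and 0.046 to 0.193 in the naive libraries. Chromosome I departed by 0.07, 0.91 and 0.53 in ESI+ replicates 1, 2 and 3, and chromosome IX by 0.05, 0.72 and 0.27. Without ESI+ replicate 2, chromosome XIII was the only chromosome past 0.3, at 0.44, and without naive replicate 1, 3 chromosomes were past it.

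**Figure D4:**
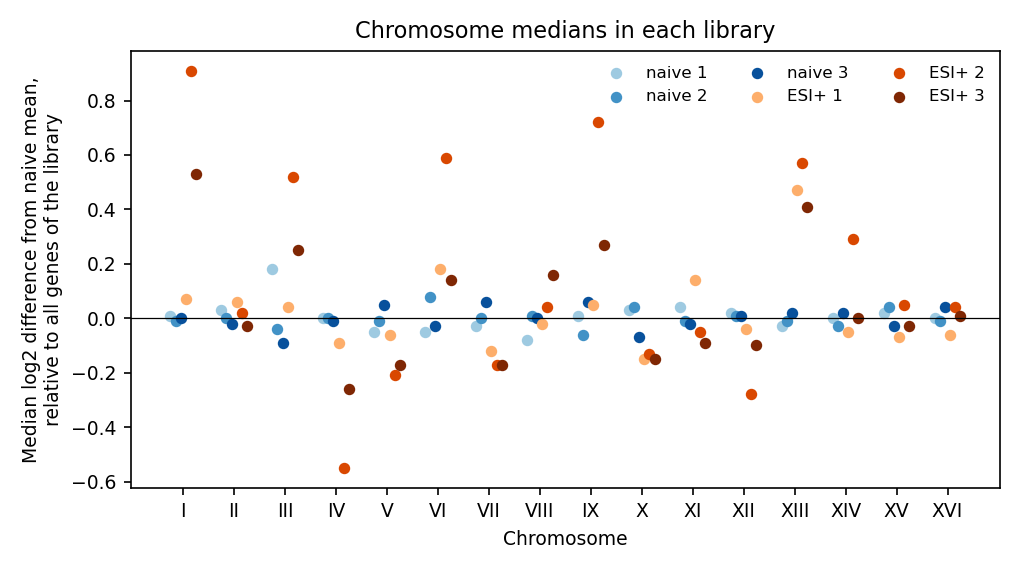
Median log2 difference from the naive mean for the genes of each chromosome, relative to all genes of the library, with 1 point per library. Chromosome XIII lies at 0.41 to 0.57 in the 3 ESI+ libraries, and chromosome I reaches 0.91 in ESI+ replicate 2.

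**Figure D5:**
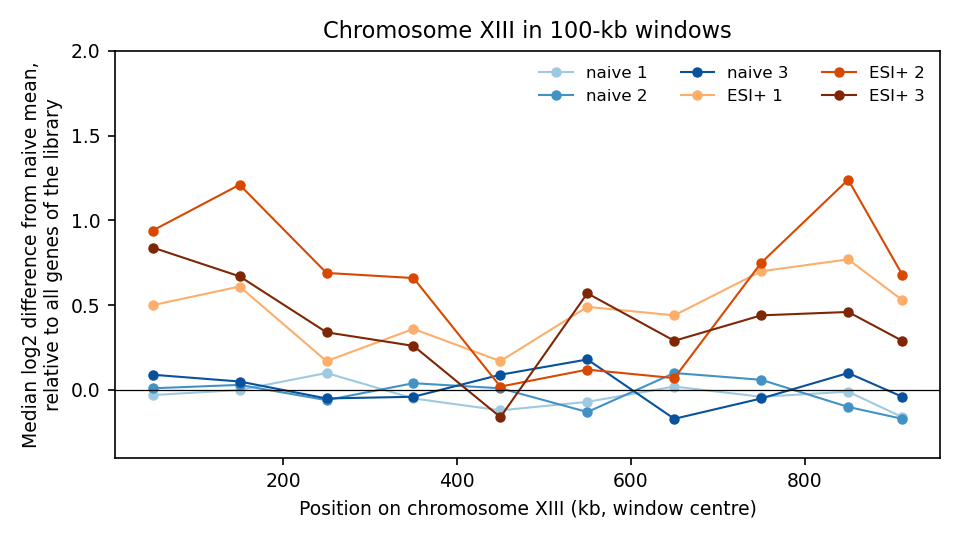
The same median difference in windows of 100 kb along chromosome XIII (kb), 1 line per library. ESI+ replicate 1 lies between 0.17 and 0.77 in all 10 windows, and ESI+ replicate 3 reaches -0.16 between 400 and 500 kb.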

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

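The settings for ESI+ replicate 1 alone, quality weights, background subtraction and chromosome XIII left out were chosen after seeing the data. The higher and lower counts (178 and 47) ranged over 2 to 331 and 0 to 87 when each library was left out. They were 96 and 20 with limma on log2(TPM + 0.1) and 41 and 1 at an adjusted p under 0.01. DESeq2 gave 241 higher and 145 lower genes, and quality weights gave 125 and 127, without the excess of higher calls. ESI+ replicate 1 alone and background subtraction gave 0 and 0 with edgeR (347 and 533 genes at an unadjusted p under 0.05). The higher and lower genes, with medians of 2.21 and -1.73 at a biological coefficient of variation of 0.465, had medians of 1.14 and -1.41 at 0.321 with ESI+ replicate 1 alone and 3.72 and -1.81 at 0.673 with background subtraction. Of the 178 and 47, 177 and 47 were tested with ESI+ replicate 1 alone and 136 and 47 with background subtraction, all with the same sign, and the lone library is assumed to vary like the naive ones. The same libraries had helped to choose these genes, so the kept sign is little evidence. The 7 higher subtelomeric genes ranged over 0 to 7 with libraries left out. They were 4 with log2(TPM + 0.1), 0 with ESI+ replicate 1 alone, with background subtraction or within 10 kb, 16 within 30 kb and 36 within 50 kb. Lower subtelomeric genes were 0 to 0 with libraries left out, 2 within 30 kb and 2 within 50 kb. The subtelomeric median was 0.35 to 0.83 with libraries left out, 0.23 with ESI+ replicate 1 alone (camera p = 0.0298), 0.96 with background subtraction (p = 1.59e-04), 1.29 and 1.32 with log2(TPM + 1) and log2(TPM + 0.1) (p = 4.53e-04 and 5.00e-04, on scales where the median of all genes was 0.65), 0.53 within 10 kb (p = 0.387), and 0.57 with an estimated correlation (p = 0.234). The number of lists that passed was 4 to 6 with libraries left out and 0 with an estimated correlation. The 5 departing chromosomes became 1 to 6 with libraries left out, 1 with ESI+ replicate 1 alone and 2 with quality weights. Chromosome XIII kept a departure of 0.41 to 0.65 in all 18 refits. The ribosome biogenesis median ran from -0.53 to 0.03 as libraries were left out, above 0 without ESI+ replicate 1. The ribosomal protein list turned without ESI+ replicate 3, with medians of 0.02 to 0.87 as libraries were left out. URA3 (0.19) was -0.03 with the block, -0.18 and -0.21 without naive replicates 1 and 2, -2.23 (without ESI+ replicate 3) to 2.22 over all libraries left out, -2.57 with ESI+ replicate 1 alone and -0.82 with quality weights, and HIS3 was -0.18 with ESI+ replicate 1 alone. The other 55 named genes kept their sign wherever they were tested. Apart from fewer libraries where some were left out, the cause was not tested.

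The replicate number as a block gave 67 higher and 25 lower genes and 3 higher subtelomeric genes. Deviations from the group means correlated at -0.064, -0.209 and -0.041 between same-numbered libraries, and no library correlated best with its own number. These values show no pairing, but they cannot exclude a shared batch, because ESI+ replicates 2 and 3 differ strongly from the rest of their group. URA3 was high in both libraries numbered 3 (254.8 and 333 normalised CPM, against 17.8 to 32.3 in the others). The 316485 counts of ESI+ replicate 3 limit what low genes can show.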

Other observations

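The genes of the 26S proteasome and of sugar use below were chosen after their values were seen, as were the tests on chromosome size and on the proteasome; leaving out each library was planned, but its use to test a background in ESI+ replicate 2 or the depth of ESI+ replicate 3 was not. Subunit genes of the proteasome, the protease complex that degrades ubiquitin-tagged proteins, had negative log2 fold changes in 25 of 25 tested members, with a median of -1.13. RPT2, RPT3, RPT5, RPN9, PRE4 and SCL1 were called lower. SCL1 had 681 ± 124 normalised CPM in naive and 203 ± 64.4 in ESI+ libraries (SD, n = 3; log2 fold change -1.75, SE 0.56, edgeR adjusted p = 0.0487). Without ESI+ replicate 2 the median was -0.85, at percentile 0.31 of lists matched on mean expression. None of the 6 was called there, where 0 of all 2841 tested genes were called lower. As the set was chosen for its called members, these values do not test whether the subunits fell together in ESI+ cells, and that stays open.

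Hexose transporter genes included HXT1, a low-affinity transporter gene, which rose by 2.23 (SE 0.54, edgeR adjusted p = 0.0136), and HXT2, which had 2.19 (SE 0.77, adjusted p = 0.0715); the list had 1 of 6 members higher and did not pass over all 6 libraries (camera adjusted p = 0.146, and 0.673 with an estimated correlation), and passed without ESI+ replicate 2 (adjusted p = 0.0368), with list medians relative to the naive mean of 1.65, 0.10 and 0.30 in ESI+ replicates 1, 2 and 3. JEN1, the lactate permease gene, and PCK1, a gene of gluconeogenesis, were higher, with log2 fold changes of 3.16 (SE 0.56, adjusted p = 0.00331) and 1.91 (SE 0.60, adjusted p = 0.0492). CIT2, a peroxisomal citrate synthase gene, was lower, with -1.77 (SE 0.50, adjusted p = 0.032). HXT1, JEN1, PCK1 and CIT2 had log2 fold changes of 2.14, 2.60, 0.75 and -2.20 without ESI+ replicate 2, where 2 of 2841 genes were called in all, and were not called there.

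Of the 178 higher calls, 140 sat among the 711 genes least abundant in naive cells, and in ESI+ replicate 2 counts of the 713 least abundant listed genes followed transcript length (Spearman's rho 0.761, against 0.04 to 0.425 in the other libraries), with 30.4% of its counts in an estimated length-proportional background against 2.45% to 6.71%; low depth of ESI+ replicate 3 is argued against by the 331 genes called higher without it. A background in ESI+ replicate 2 with no shift elsewhere was examined with the 178 genes most raised in it against naive replicate 2. In ESI+ replicate 1 against naive replicates 1 and 3 they had a median of 1.18, at percentile 100 of 10000 matched lists, whose median was 0.58. The matching mean includes the ESI+ values, so these genes are set beside genes more abundant in naive cells. With ESI+ replicate 1 alone, the 711 genes least abundant in naive cells had a median of 0.49 and the 711 most abundant -0.46. The percentile therefore cannot decide whether the shift was confined to ESI+ replicate 2. The higher calls without ESI+ replicate 2 were 2, against 249 and 331 without ESI+ replicates 1 and 3. The lower calls were 0, against 87 and 43. Leaving out naive replicates 1, 2 and 3 also cut the counts, to 87, 63 and 71 higher and 14, 6 and 4 lower calls. The higher calls fell furthest without ESI+ replicate 2. For the lower calls, 1 library fewer may account for most of the loss. Without ESI+ replicate 2, the 177 of the 178 higher genes still tested had a median of 1.67 (from 2.21). The 47 lower genes had -1.69 (from -1.73), and the biological coefficient of variation was 0.391 (from 0.465). All kept their sign, but these genes were chosen in a fit that held ESI+ replicates 1 and 3. The kept sign therefore cannot show that the calls do not rest on ESI+ replicate 2. A background proportional to transcript length in ESI+ replicate 2 stays a candidate explanation for part of the higher folds, and a milder form of it in replicate 1 or a rise of the genes in the ESI+ state stays open. The 6 libraries have 10 splits into 3 and 3, too few for a share under 0.05, and the real split (1 of the 10) called 225 genes with edgeR and the highest other 0 (at most 234 at an unadjusted p under 0.05).

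Chromosome XIII genes were higher in each ESI+ library. A background that depends on chromosome size is argued against as the whole cause. In the mean of the ESI+ libraries, chromosome XIII lay 5.21 residual SDs above a line of departure on log length. The line was drawn through the other 15 chromosomes. By library, chromosome XIII lay 7.13, 3.12 and 4.16 residual SDs above the line in ESI+ replicates 1, 2 and 3. GC content, length and abundance are argued against by a departure of 0.49 in ESI+ replicate 1 after regression on them, against 0.47 before. An extra copy of chromosome XIII in the ESI+ cultures is a candidate explanation, with 100% of its 100-kb windows above 0 in ESI+ replicate 1, although the windows ran from 0.17 to 0.77 there and the window from 400 to 500 kb was at 0.02 and -0.16 in ESI+ replicates 2 and 3. The windows from 500 to 600 and 600 to 700 kb were also near 0 in ESI+ replicate 2 (0.12 and 0.07), against 0.49 and 0.44 in replicate 1 and 0.57 and 0.29 in replicate 3. A change in how these genes are expressed in the ESI+ state also stays open, as DNA was not analysed here.

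Heat shock genes were lower in each ESI+ library. A background in ESI+ replicate 2 is argued against as the whole cause, since the list passed camera without that library (median -0.89, from -1.17, adjusted p = 2.00e-04, with 4.74e-10 to 0.00141 over the 18 refits, all with the preset correlation). The list median without that library lay at percentile 1.16 of lists matched on mean expression. That mean includes the ESI+ values, so falling genes are set beside genes less abundant in naive cells. The percentile therefore cannot decide whether compression of abundant genes is the whole cause. A lower heat shock expression in ESI+ cells stays a hypothesis, since the list did not pass with an estimated correlation (adjusted p = 0.673), and differences in how the cultures were grown stay open and untested.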
